A study of Homo sapiens with 12 samples.

How the data were processed

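Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 12 libraries of MCF-7, a human breast adenocarcinoma cell line. The libraries fell into 3 groups of 4: untreated cells, cells given 0.3 µM GQC-05 for 72 h and cells given 20 µM GTC365 for 72 h, as the labels state. Both compounds are G-quadruplex (G4) stabilising ligands per the labels. Each group held libraries 1a, 1b, 2a and 2b. The labels do not say whether these came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

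The values used were peak lists deposited by the authors, 1 list per library with no pooling of replicates. Per the submitters' processing notes, cutadapt, BWA, SAMtools, Picard, MACS2, bedtools and edgeR were used on build hg19; their versions and parameters are not given in the sources used here. The deposited lists give each peak's start, end and summit in bp. They also give the caller's fold enrichment, a ratio of pileup to background computed by the authors. The deposited −log10 p-value and −log10 q-value per peak are the caller's. The deposited score per peak was 10 times the −log10 q-value, cut to a whole number. The smallest −log10 q-value in a list lay between 1.30 and 1.31 in all 12 lists. Folds, scores and q-values are the authors' and were used only to describe, rank or filter peaks within a list. Read counts were not used here, so the precision of a single peak is not known from reads.

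Depth was read from the lists through the caller's own formulas. For every 20th peak, the whole-number pileup at the summit and its background were solved from the fold and the −log10 p-value, and the solution was accepted within 0.01 of the deposited −log10 value. A solution was found for 100% of the peaks tried in each library. The most frequent background of a list served as its genome-wide background pileup, in fragments covering a base. On simulated peaks the procedure recovered 191 of 191.

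Peaks of all 12 lists were merged into union regions with bedtools 2.31.1. A region counted as called in a library when a peak overlapped it by at least 1 bp. A region was termed gained when called in 4 of 4 libraries of the first group and 0 of 4 of the second, and lost in the reverse case. With 4 libraries against 4, the smallest two-sided p of Fisher's exact test and of the exact permutation test is 0.0286. Of the 65845 to 78927 regions tested per comparison, 126 to 245 reached it and 0 passed Benjamini-Hochberg adjustment. Only gained and lost regions can reach that p in Fisher's exact test. With so many regions tested, passing the adjustment was almost impossible by design, so 0 passing does not speak against a change. Counts of gained and lost regions were set against all 35 splits of the 8 libraries of a comparison. Measures with 1 value per library were compared by a two-sided exact permutation test over 70 assignments, adjusted by Benjamini-Hochberg over 9 measures per comparison. The similarity of libraries was the Jaccard index of covered bp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

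The counting of regions was tested on simulated data, with 200 regions planted per comparison. For GQC-05 versus untreated, 91.0% of planted regions were recovered in deposited lists when called with a chance of 99% in one group and 1% in the other, and 49.5% with chances of 90% and 5%. For GTC365 versus untreated these shares were 90.5% and 58.0%, and for GQC-05 versus GTC365 they were 95.0% and 55.5%. Planted regions were called in the wrong direction 0 times. Regions that were not planted, simulated with 1 call chance for both groups, also gave calls in deposited lists. These numbered 146 and 164 for GQC-05 versus untreated, 181 and 196 for GTC365 versus untreated, and 136 and 147 for GQC-05 versus GTC365.

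The comparisons, the tests on peak number, regions, similarity and overlap, and the rule for named regions were set before the data were examined. So were a stricter threshold (−log10 q of at least 5), lists of equal length, a sharing of at least 50% of peak and region, calls in at least 3 against at most 1 library, a replicate block, each label letter alone, the label number as the unit, and leaving out each library, each for the results it was planned for. Leaving out each library for similarity and for the overlap of both compounds, and the stricter threshold for that overlap, were added after the data had been seen. For lists of equal length, the 18463 peaks with the highest −log10 q were kept in every library, the number of the shortest list. The named-region rule took, per comparison and direction, the 2 regions with the largest difference in libraries called, ordered next by the mean within-list percentile rank of −log10 q. Regions outside chromosomes 1 to 22 and X were not named. No filter for mappability or repeats was applied here, so a named region may lie in sequence prone to artefacts.

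Peak width, shortest peak, shares per chromosome, fixed peak ends, mitochondrial summits and the grouping of chromosomes by base composition were chosen after the data had been seen. The grouping took chromosomes 16, 17, 19, 20 and 22 as GC-rich and 3, 4, 5, 6, 13 and X as GC-poor. A comparison of the GC-rich share with peak length was also tried, and was dropped after its value had been seen because it could not decide between explanations. A gene annotation or genome sequence of hg19 was not used here, so promoters, gene lists, sequence motifs and G4 motifs were not analysed here, and regions are given by hg19 coordinates alone.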

Results

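Accessible chromatin was profiled in MCF-7 breast adenocarcinoma cells left untreated or exposed for 72 h to a G4-stabilising ligand, with 4 ATAC-seq libraries per group. The design asks whether G4 stabilisation changes chromatin organisation. The doses differed, at 0.3 µM for GQC-05 and 20 µM for GTC365. Untreated libraries 1a, 1b, 2a and 2b held 49654, 33908, 21506 and 24174 peaks. GQC-05 libraries in the same order held 35108, 30256, 18463 and 29564 peaks, and GTC365 libraries held 26060, 38357, 44345 and 30009. The genome-wide background pileup, an index of depth, ran from 0.502 to 2.29 fragments per base over the 12 libraries. The lists merged into 84679 regions, of which 8959 (10.6%) were called in all 12 libraries and 33278 (39.3%) in 1 library only.

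Under GQC-05, 18 regions were gained and 108 were lost relative to untreated cells. The first gained region by the fixed order lay at chr7:45291577-45291706 (hg19, 130 bp), and the next at chr3:160665442-160665571 (130 bp). Both were called in 4 of 4 GQC-05 libraries, 0 of 4 untreated and 0 of 4 GTC365 libraries, at mean percentile ranks of 99.96 and 99.4 within their lists. The ends of all 8 peaks at these regions lay within 3 bp of the median ends of their region, whereas the ends of the other gained regions varied by a median of 253.5 bp. The first lost regions were chr1:81719927-81720472 (546 bp) and chr6:8590638-8590880 (243 bp), called in 4 of 4 untreated and 0 of 4 GQC-05 and GTC365 libraries.

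Gained regions under GQC-05 lay on the GC-rich chromosomes 16, 17, 19, 20 and 22 in 6 of 18 cases (33.3%), lost regions in 5 of 108 (4.63%) and all regions of the 2 groups in 11.1%. The gap between gained and lost, 28.7 points, was reached by 2 of the 10 splits with at least 10 regions in each direction, the highest other being 30.8. Over whole lists, these chromosomes held 12.1% ± 0.290 of peaks under GQC-05 and 10.3% ± 0.264 in untreated cells (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0857). All 4 GQC-05 libraries lay above all 4 untreated libraries. Chromosome 19 held 1.98% ± 0.150 of peaks under GQC-05 against 1.298% ± 0.184 in untreated cells (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0762 over 24 chromosomes and contigs). Chromosomes 15, 16 and 17 were also higher at this p, and chromosomes 1, 2, 3, 4 and 6 lower. Chromosomes 16 and 19 remained higher and chromosome 1 lower in lists of equal length (exact permutation p = 0.0286, adjusted p = 0.206). The chromosome grouping was set after the shares had been seen. Within each of the 2 series of library codes, the difference in GC-rich share was 1.81 percentage points.

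The total of 126 regions gained or lost under GQC-05 was reached by 11 of the 35 splits of the 8 libraries. By definition these 126 had the smallest possible unadjusted p of Fisher's exact test, 0.0286. With so few regions at that p, 0 could pass Benjamini-Hochberg adjustment. With lists of equal length, 77 regions were gained and 102 lost, and 1 of 35 splits, the real one, gave as many. Leaving out GQC-05 2a gave 140 gained regions and leaving out untreated 2a gave 488 lost regions, the highest of the 8 such counts in each direction. Of the 18 gained and 108 lost regions, 5 and 24 were also called in lists of equal length. A region gained or lost only in lists of equal length had a peak in a deposited list of the opposite group. Those counts thus rest partly on the rank of peaks, not on their presence or absence alone. Peak number did not separate the groups, at 28348 ± 7036 under GQC-05 and 32311 ± 12732 in untreated cells (SD, n = 4 each, exact permutation p = 0.657). The shortest peak of a list was 114.5 ± 13.03 bp under GQC-05 and 133 ± 2.16 bp in untreated cells (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0857). This difference was −7 bp between libraries of letter a and −30 bp between those of letter b, which are the 2 code series. With each of the 4 untreated libraries left out in turn, the difference stayed between −19.2 and −17.5 bp but did not pass (exact permutation p = 0.0571 to 0.0857). All 4 GQC-05 libraries still lay below every remaining untreated library, so the higher p does not reflect overlap of the groups.

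**Figure D1:**
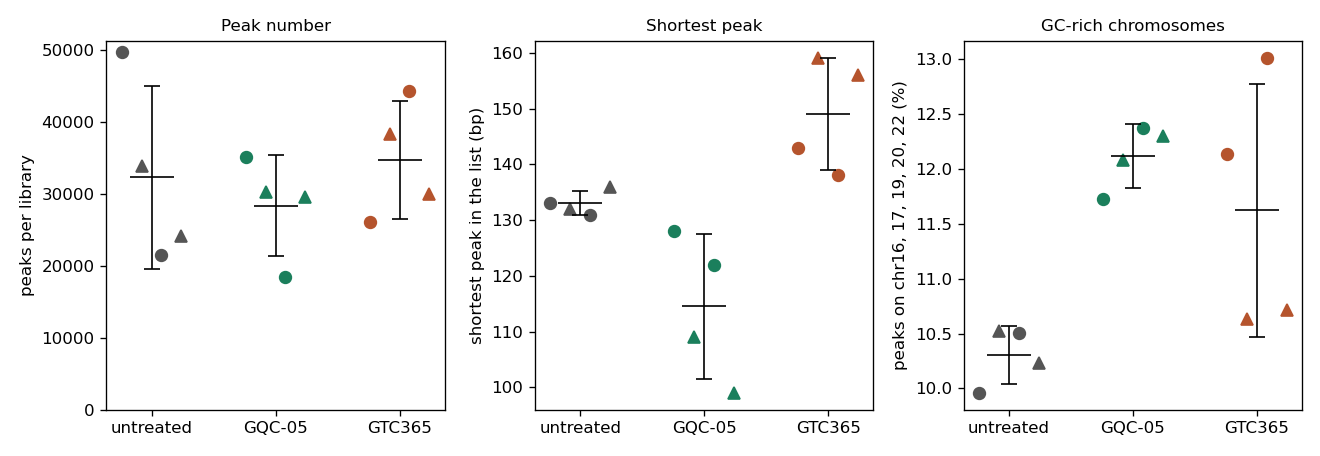
Peaks per library (left), shortest peak of each list in bp (centre) and percent of peaks on chromosomes 16, 17, 19, 20 and 22 (right) in untreated, GQC-05 and GTC365 libraries, with circles for letter a, triangles for letter b, and the mean with SD over 4 libraries. Shortest peaks spanned 99 to 128 bp under GQC-05, 131 to 136 bp in untreated cells and 138 to 159 bp under GTC365.

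Under GTC365, 112 regions were gained and 98 lost relative to untreated cells. The first gained regions were chr8:46852295-46852952 (658 bp), also called in 4 of 4 GQC-05 libraries, and chr2:89858860-89859293 (434 bp), called in 1 of 4 GQC-05 libraries. Neither was checked for mappability or repeats here. The first lost regions were chr1:77436909-77437101 (193 bp), called in 4 of 4 GQC-05 libraries, and chr12:86769785-86770149 (365 bp), called in 2 of 4. Gained regions lay on GC-rich chromosomes in 21 of 112 cases (18.8%), lost regions in 4 of 98 (4.08%) and all regions of the 2 groups in 11.3%. The gap between gained and lost, 14.7 points, was reached by 8 of the 16 such splits, the highest other being 36.3. GC-rich chromosomes held 11.6% ± 1.15 of peaks under GTC365 and 10.3% ± 0.264 in untreated cells (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.129).

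That difference in GC-rich share, 1.32 percentage points, was 1.25 points in lists of equal length (exact permutation p = 0.143). It was 2.34 points between libraries of letter a and 0.301 between those of letter b, and 1.39 points within the single code series that held GTC365. The untreated libraries of letter b were of the other code series, so letter and code cannot be told apart there. With each of the 4 untreated libraries left out in turn, the difference in share stayed between 1.20 and 1.39 points. The exact permutation p was then 0.114 to 0.143. All 4 GTC365 libraries still lay above every remaining untreated library in these fits. Over all single libraries left out, the difference ranged from 0.857 (without GTC365 2a) to 1.65 points (without GTC365 1b). Chromosome 21 held more peaks under GTC365 and chromosomes 1, 2 and 11 held fewer (exact permutation p = 0.0286, adjusted p = 0.171). Chromosomes 2, 9 and 11 were lower, and chromosomes 14, 18 and 20 and the unplaced contigs higher, in lists of equal length (exact permutation p = 0.0286, adjusted p = 0.0980).

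The total of 210 regions gained or lost under GTC365 was reached by 7 of the 35 splits. By definition these 210 had the smallest possible unadjusted p of Fisher's exact test, 0.0286, and 0 could pass Benjamini-Hochberg adjustment. Lists of equal length gave 114 gained and 123 lost, a total reached only by the real split of the 35. Leaving out untreated 1a gave 484 gained regions and leaving out untreated 2a gave 409 lost regions, the highest of the 8 such counts in each direction. Of the deposited-list regions, 17 of 112 gained and 37 of 98 lost were also called in lists of equal length. As for GQC-05, the counts in those lists rest partly on peak rank. Peak number was 34693 ± 8227 under GTC365 (SD, n = 4, exact permutation p = 0.771 against untreated). The shortest peak was 149 ± 10.1 bp, longer in all 4 libraries than in any untreated library (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.129). The difference was 17 bp within the code series that held GTC365, 8.5 bp for letter a and 23.5 bp for letter b. For letter b the untreated libraries were of the other code series. Without each of the untreated libraries in turn, the difference in shortest peak stayed between 15.3 and 17 bp, with an exact permutation p of 0.0571. The groups still did not overlap in these fits.

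**Figure D2:**
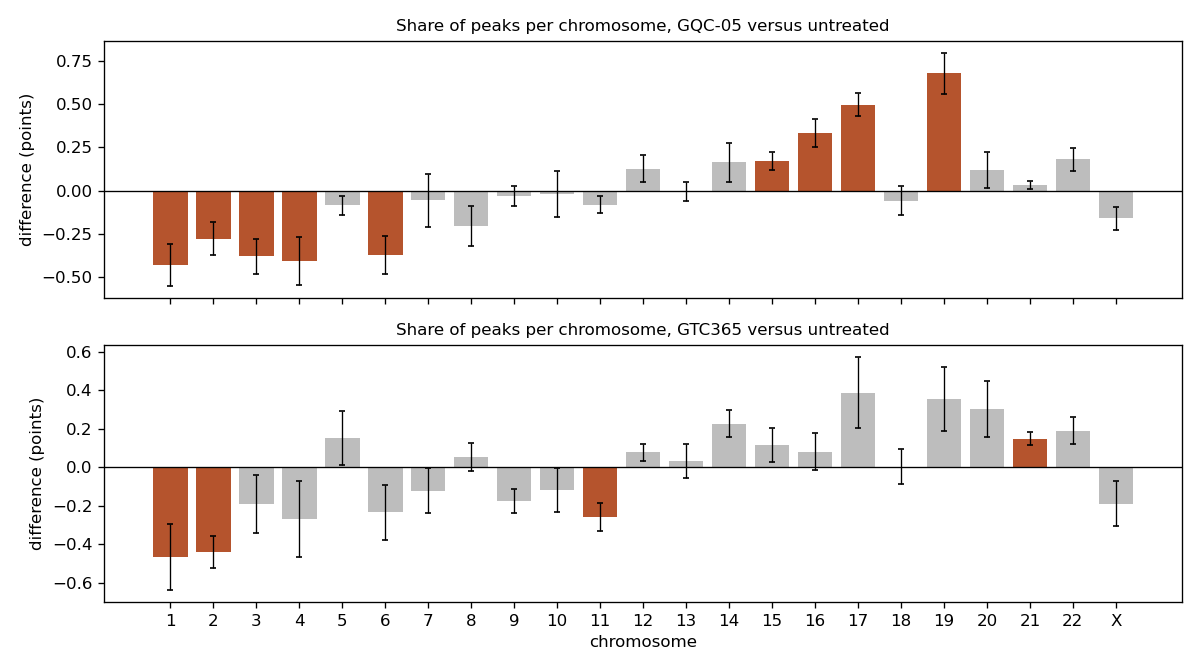
Difference in the percent of peaks on each chromosome, compound minus untreated in percentage points, with bars in orange where the exact permutation p was 0.0286 and error bars of 1 standard error of the difference over 4 and 4 libraries. Chromosome 19 differed by 0.680 points under GQC-05 and 0.357 points under GTC365.

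Between the compounds, whose doses differed, 41 regions were called in 4 of 4 GQC-05 and 0 of 4 GTC365 libraries, and 204 showed the reverse. The highest counts on leaving out a library were 203 without GQC-05 2a and 701 without GTC365 1a. The regions first under GQC-05 were those on chromosomes 7 and 3 given above. The regions first under GTC365 were chr1:142542101-142542747 (647 bp), called in 0 of 4 untreated libraries, and chr9:68704690-68704927 (238 bp), called in 1 of 4. These too were not checked for mappability or repeats. Lists of equal length gave 83 and 97 regions. The total of 245 was reached by 4 of the 35 splits in deposited lists, and that of 180 by the real split alone in lists of equal length. By definition the 245 had the smallest possible unadjusted p of Fisher's exact test, 0.0286, and 0 could pass Benjamini-Hochberg adjustment. All 12 entries named by the fixed order in the 3 comparisons kept 4 of 4 against 0 of 4 in lists of equal length. The regions on chromosomes 7 and 3 are entered in 2 of the comparisons. Since these lists are parts of the deposited lists, 0 of 4 was fixed in advance. The 4 of 4 was favoured, since −log10 q both ordered the entries and decided which peaks were kept.

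Peaks were narrower under GQC-05 than under GTC365, with a median width of 254.75 ± 27.9 bp against 311.25 ± 10.6 bp (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.129). In lists of equal length the difference was −100.5 bp with an exact permutation p of 0.114. Without each of the GTC365 libraries in turn it stayed between −60.6 and −52.9 bp with an exact permutation p of 0.0571, though the groups still did not overlap. The GC-rich share differed by 0.494 percentage points (exact permutation p = 0.371), by 0.165 to 0.956 with single libraries left out, and by −0.525 points between libraries of letter a and 1.51 between those of letter b. The GQC-05 libraries of letter b were of the code series that did not hold GTC365.

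**Figure D3:**
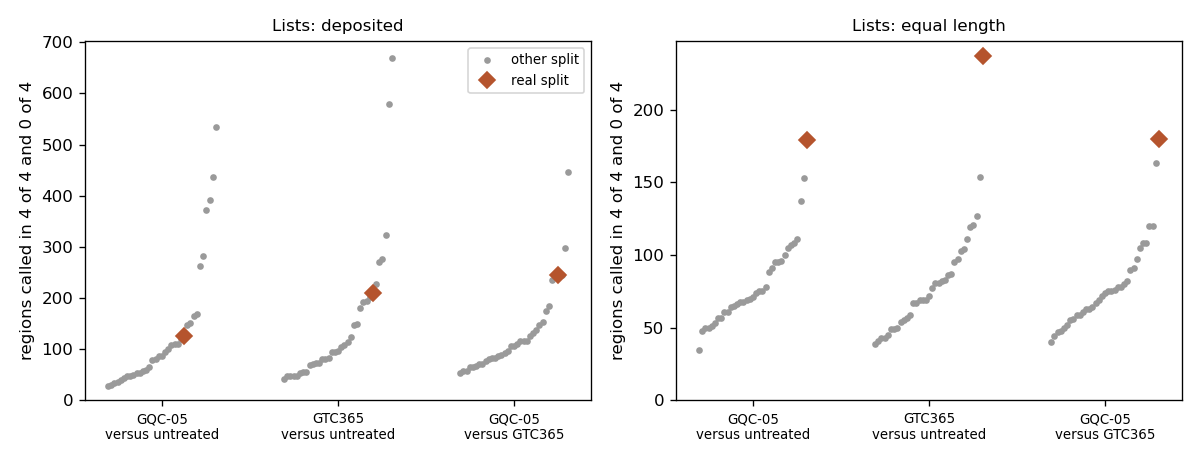
Number of regions called in 4 of 4 libraries on one side and 0 of 4 on the other, for each of the 35 splits of the 8 libraries of a comparison, in deposited lists (left) and lists of equal length (right), with the real split as an orange diamond. The real totals were 126, 210 and 245 in deposited lists and 179, 237 and 180 in lists of equal length.

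Gained regions shared by both compounds numbered 3 in deposited lists, against a mean of 4 (range 0 to 10) in 100 simulations of unchanged groups set against the same untreated libraries and 0.0238 for independent lists. Lost regions shared by both numbered 22, against a simulated mean of 13.84 (5 to 21) and 0.125. Leaving out a single untreated library gave up to 125 shared lost regions (without 2a), with 85 without 2b and 42 without 1b, and up to 28 shared gained regions (without 1a), with 14 without 1b. Leaving out GTC365 1b gave 37 shared lost regions, and leaving out GQC-05 2a, GQC-05 1a and GTC365 1a gave 12, 7 and 5 shared gained regions. In lists of equal length the shared gained regions numbered 9 (simulated mean 3.79, range 0 to 11) and the shared lost regions 29 (simulated mean 5.45, range 1 to 12). Both comparisons use the same untreated libraries, and splitting these into separate pairs leaves the shared count unchanged by construction. Part of any excess over independent lists may therefore come from them. The simulated values already include these shared libraries, but only as far as the simulation models the call chances. The Jaccard index within groups exceeded that between groups by 0.0110 for GTC365 versus untreated in deposited lists (5 of 35 splits as large), and by 0.0226 in lists of equal length (1 of 35). This excess was 0.00591 at the stricter threshold (11 of 35), and ranged from 0.00248 to 0.0263 with single libraries left out. For GQC-05 versus untreated the excess was 0.000694 (11 of 35 splits) in deposited lists and 0.00965 (5 of 35) in lists of equal length, but −0.00292 at the stricter threshold, and it ranged from −0.00769 to 0.0107 with single libraries left out. Between the compounds it was 0.0256 (3 of 35) and 0.0281 (2 of 35), and the former ranged from 0.0120 to 0.0418 with single libraries left out.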

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

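The tests of explanations in this part were chosen after the results had been seen; the counting of splits was set beforehand, and its bounds were written down afterwards. In 1 library a value stood apart from its group: the genome-wide background pileup of GQC-05 library 2a was 0.502 fragments per base. Of 27 groups of 4 values examined, 1 stood out, where the nominal rate of the rule is about 1 in 20, which was not measured here.

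The first pattern is the pair of regions ranked first among those gained under GQC-05. The region on chromosome 7 had the highest fold of its list in all 4 GQC-05 libraries. All 8 peaks of the pair had both ends within 3 bp of their region's median ends. Of the 35447 regions called in at least 4 libraries, 5 (0.0141%) had ends that varied by at most 3 bp, the pair included. Among the 4616 regions called in exactly 4 libraries it was 3, the pair included. A candidate explanation is a molecule with fixed ends, such as an amplified or carried-over fragment, aligned to these sites. Fixed ends also occurred without treatment, in 1 region called in all 12 libraries at folds of 33.5 to 66.3. That region does not show that open chromatin gives such ends. Opening of chromatin was not told apart from such a molecule, because mappability was not used here.

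The second pattern is the shortest peak of a list, which separated the 3 groups. Against list length and depth as the whole explanation stood the untreated libraries, whose shortest peaks lay within a range of 5 bp although their lists ran from 21506 to 49654 peaks. Against library code as the whole explanation stood the shift within a single series of codes, −7 bp for GQC-05 and 17 bp for GTC365. Fragment size selection in library preparation may contribute: the difference of letter b minus letter a was 17 bp under GTC365, −21 bp under GQC-05 and 2 bp in untreated cells. Under GTC365 both letters were of a single code series, while in the other groups the letters differed in code series, so these values are not alike. Fragment size selection cannot be told apart from an effect of the compounds on fragment length, which the design leaves untested. In each list 112 to 222 peaks tied at exactly the shortest length, so the value may be a lower limit set in peak calling. The caller's parameters are not given in the sources used here, so this was not tested.

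The third pattern is the higher share of peaks on GC-rich chromosomes. For GQC-05, the difference was 1.99 percentage points in lists of equal length (exact permutation p = 0.0286). Cutting to equal length removed more from longer lists, and the share then fell as the deposited list grew. It fell from 10.1% (untreated 2a) to 7.88% (untreated 1a), and from 12.4% (GQC-05 2a) to 10.5% (GQC-05 1a). This cut therefore cannot decide on list length, although all GQC-05 libraries still lay above all untreated ones. For GTC365, the difference of 1.25 points in lists of equal length had an exact permutation p of 0.143, and list length cannot be told apart from the compound. GC bias in amplification may also contribute, but the values here cannot decide on it. The untreated libraries alone spanned 2.27 points in lists of equal length, though 1.02 points without untreated 1a and 0.559 points in deposited lists. The wider span followed the order of deposited list length, so it is not evidence of such a bias. An effect of either compound on GC-rich chromatin remains open.

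Chance could not be excluded for the regions gained or lost in deposited lists. For GQC-05 versus untreated, 11 of 35 splits gave at least the real total of 126, the highest other being 534. For GTC365 versus untreated it was 7 splits, with 210 and a highest other of 670, and for GQC-05 versus GTC365 it was 4 splits, with 245 and 447. The split with 534 set libraries numbered 1 against those numbered 2, and that with 670 set GTC365 1b and 2a with untreated 1a and 1b against the rest. Both put the 4 longest of the 8 lists on one side, and with lists of equal length they gave 105 and 95, so the high totals went with list length. In lists of equal length 1 of 35 splits, the real one, was as large in each comparison: 179 against a highest other of 153, 237 against 154 and 180 against 163. If libraries are independent units, which the labels do not say, a chance split was thereby excluded at the 0.05 level for each comparison alone. This is the smallest share that 35 splits allow, it is not adjusted for 3 comparisons that share libraries, and it does not tell treatment from a technical difference between the groups. Regions counted only in lists of equal length had a peak in a deposited list of the opposite group, so these totals rest partly on peak rank.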

How the results depend on the processing

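The alternatives for peak width, shortest peak and GC-rich share, the restriction to a single library code series, leaving out each library for similarity and for the overlap of both compounds, and the stricter threshold for that overlap were chosen after the data had been seen. Over 23 results, 197 of 314 alternative values kept their side of the threshold or stayed within the spread, 117 did not, and 0 called values reversed, though some values that passed no test changed sign. The cause of these changes was not tested, except that fewer libraries or looser criteria admit more regions by construction. Regions gained and lost are given in that order for GQC-05 versus untreated, GTC365 versus untreated and GQC-05 versus GTC365, with unlisted counts within 1.5 times the main value. The stricter threshold gave 10 gained for the first, 39 gained for the second, and 23 and 74 for the third. Lists of equal length gave 77 gained for the first, and 83 and 97 for the third. Sharing of 50% gave 6 gained for the first, 49 lost for the second, and 19 and 347 for the third. Calls in at least 3 against at most 1 library gave 1157 and 2542, 2653 and 2032, and 1172 and 3378. The label number as the unit gave 388 and 1009, 1007 and 991, and 644 and 1488. A single code series gave 266 and 1729, 240 and 666, and 210 and 581. Regions shared by both compounds were 9 gained in lists of equal length, and 470 gained and 1043 lost at 3 against 1. The excess similarity for GTC365 versus untreated was 0.0226 in lists of equal length and then passed the threshold. At the stricter threshold for peaks it was 0.00591 and did not pass (11 of 35 splits as large).

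Median width for GTC365 versus untreated differed by 64 bp at the stricter threshold and then passed (exact permutation p = 0.0286), and GQC-05 versus GTC365 by −100.5 bp in lists of equal length and then did not. The shortest peak differed, for letters a and b, by −7 and −30 bp (GQC-05 versus untreated), 8.5 and 23.5 bp (GTC365 versus untreated) and −15.5 and −53.5 bp (GQC-05 versus GTC365). The GC-rich share for GTC365 versus untreated was 1.32 points at the stricter threshold, 1.25 in lists of equal length and 1.02 without chromosome 20, with exact permutation p-values of 0.0857, 0.143 and 0.0571, and 2.34 and 0.301 for letters a and b. For GQC-05 versus GTC365 the letters gave −0.525 and 1.51. In both comparisons with GTC365, the libraries of letter b differed in code series as well as in treatment.

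With each library left out in turn, gained and lost regions ranged from 21 to 140 and 126 to 488 (GQC-05 versus untreated), 126 to 484 and 110 to 409 (GTC365 versus untreated), and 53 to 203 and 232 to 701 (GQC-05 versus GTC365). The extremes came without GQC-05 2a (140 and 203), untreated 2a (488 and 409), untreated 1a (484) and GTC365 1a (701). Regions shared by both compounds ranged from 3 to 28 gained and 25 to 125 lost, highest without untreated 1a and 2a. Median width ranged from −43.6 to −20.9, 19.9 to 30.9 and −68.6 to −45.9 bp in the 3 comparisons, from −31.5, 25 and −56.5 bp with all libraries (exact permutation p = 0.0857, 0.0571 and 0.0286). It passed at −43.6 bp without GQC-05 1a and at 30.9 bp without untreated 1a (exact permutation p = 0.0286 each). The shortest peak ranged from −23 to −13.3, 12.7 to 19.7 and −39 to −29.3 bp. It did not pass in 4, 4 and 1 of the 8 fits (highest exact permutation p = 0.0857, 0.0571 and 0.0571), though the groups still did not overlap. The GC-rich share for GTC365 versus untreated ranged from 0.857 (without GTC365 2a) to 1.65 points (without GTC365 1b). It did not pass in the 4 fits without an untreated library, at 1.20 to 1.39 points, though the groups still did not overlap. Peak number, which passed in 0 comparisons, changed sign: GQC-05 versus untreated from −7564 to 1818 with single libraries left out and 869 for letter b, and GTC365 versus untreated from −1219 to 8163 and −2320.5 at the stricter threshold. The excess similarity ranged from −0.00769 to 0.0107, 0.00248 to 0.0263 and 0.0120 to 0.0418.

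The labels number libraries alike in each group. For GTC365, the labels were not found to pair its libraries with those of either other group. Between GQC-05 and untreated libraries a weak link by label cannot be excluded, and the unpaired tests ignore it. Correlations of deviations between same-labelled libraries in deposited lists ran from 0.0224 to 0.0688 for GQC-05 and untreated (4 of 4 best with their own label). They ran from −0.0142 to 0.0183 for GTC365 and untreated (0 of 4), and from −0.0368 to −0.000256 for GQC-05 and GTC365 (0 of 4). In lists of equal length they ran from 0.0140 to 0.0975 (3 of 4), −0.0774 to 0.0151 and −0.0496 to 0.00401 (0 of 4 each). With the replicate block, 370 and 1191, 1170 and 966, and 461 and 1802 regions were gained and lost. Peak number differences of −3962.75, 2382.25 and −6345, which the block leaves as they are by construction, had exact sign-flip p-values of 0.5, 0.75 and 0.625, and 0.125 is the smallest p that 4 pairs allow. Promoters, promoter and G4 motif shares, gene lists and motifs, with their alternatives, were not run. How depth limits the calls was not tested: untreated 1a had 49654 peaks at a background pileup of 0.939, and GQC-05 2b had 29564 at 0.983.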

Other observations

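The summit of the peak over the mitochondrial genome was examined after the data had been seen. The summit lay within 10 bp of position 15416 (hg19) in 4 of 4 untreated libraries, 3 of 4 GQC-05 libraries and 0 of 4 GTC365 libraries. The position was taken from the untreated libraries, so the difference was not tested. In GTC365 libraries 1a, 2a and 2b the summit lay at 12750, as in GQC-05 library 1a, and in GTC365 library 1b at 11624. The ratio of mitochondrial to nuclear background was 22395 ± 6184 in untreated cells, 16397 ± 7893 under GQC-05 and 12619 ± 5978 under GTC365 (SD, n = 4 each, exact permutation p = 0.286 and 0.143 against untreated). The mitochondrial background was taken at each library's own summit. Since the summits differed between groups, these ratios were measured at unlike positions and cannot be compared as amounts of mitochondrial DNA.

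Unplaced contigs held 0.587% ± 0.0792 of peaks in untreated cells, 0.783% ± 0.117 under GQC-05 and 0.815% ± 0.176 under GTC365 (SD, n = 4 each, exact permutation p = 0.0571 and 0.0857 against untreated). GC-poor chromosomes held 29.8% ± 0.281 of peaks under GQC-05 and 31.2% ± 0.506 in untreated cells (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0857). Under GTC365 they held 30.5% ± 1.41 (n = 4, exact permutation p = 0.457). Among lists of equal length, 24 of 77 regions gained under GQC-05 (31.2%) and 4 of 102 lost (3.92%) lay on GC-rich chromosomes. This gap of 27.2 points was reached by 2 of the 35 splits, the highest other being 27.3. Under GTC365 the gap was 11.7 points and was reached by 12 of 35 splits.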
